A study of Mus musculus with 2 samples.

How the data were processed

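Retinal RNA of 1 wild-type and 1 Sox11 knockout mouse embryo, littermates at embryonic day 18 per the labels, was measured on 1 Affymetrix mouse array each. Per the labels' protocols, total RNA was extracted with a column kit, turned into cDNA from an oligo-dT primer carrying a T7 promoter, amplified, transcribed into biotin-labelled cRNA and fragmented. The deposited values are probe set intensities on a linear scale, 1 per probe set and array, as the authors scaled them. The software and its settings are not given in the sources used here. That the arrays were scaled to a common target was read from the values: the mean over all probe sets after leaving out 2% at each end was 100 on both arrays, and no value was below 0. Detection calls were not used here. The labels gave each array its genotype, and no column lay outside the series.

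The 64 control probe sets of the array were left out, which left 45037. Intensities were turned to log2(intensity + 5), where 5 is the 25th percentile of the pooled values of both arrays, and no further normalization was applied between arrays. Ratios are knockout minus wild type on that scale, so the change of low genes is understated. A probe set entered counts and gene values if the higher of its 2 intensities was at or above 18.6, the pooled median; 23581 probe sets (52.4%) did. Where the dimmer array of a named gene was below 18.6, the brighter intensity over 18.6 was given as a lower bound of the fold, and list medians were also taken with such values set to 18.6. Without detection calls, that value stands in for the background.

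Probe sets were named from GEO's platform annotation, which gave 1 gene symbol for 34945 probe sets, several for 932 and none or no entry for 9160, which stay unnamed here. Of those with 1 symbol, 34741 matched a gene table of assembly GRCm38.p6 through their Entrez number, and no symbol changed. That table was used only for names, for which chromosome a gene is on and for which genes neighbour each other. Probe sets with several symbols were not named. A gene took the value of its passing probe set with the highest mean log2 value, which gave 11557 genes, 5612 of them with several passing probe sets. The pooled SD of log2 ratios between probe sets of a gene was 0.26. Of 30 genes with several probe sets and a 2-fold difference, 26 had all probe sets on the same side.

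With 1 array per genotype there is no spread between animals and no test. Probe sets at least 2-fold apart were counted, and 34 gene lists were compared with 10000 random lists each, of the same size and matched on mean log2 value in 20 bins. A list with at least 4 members past the filter was called outside if the percentile of its median was under 2.5 or over 97.5. The lists covered the SoxC family, 10 types of retinal cells and precursors, the cell cycle, p53 targets, neuronal cytoskeleton, synapse, 3 signalling pathways, other tissues that the sample could hold, sex-linked genes, stress and reference genes. Genes were named by rule: Sox11, Sox4 and Sox12, the 12 highest and 12 lowest genes whose probe sets shared a sign, and up to 4 members per list with the largest ratios. The measures, filter, pseudocount, lists, naming rule and alternatives were chosen before the data were examined, except where stated.

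The alternatives were centring on the median log2 ratio, quantile normalization, loess with a span of 0.3, no pseudocount, a pseudocount at the pooled median, no low-value filter, a filter at the pooled 75th percentile of 109.4, leaving out probe sets that can match several transcripts (with an s, x or a in the suffix), the median over the probe sets of a gene, and random lists not matched on level. Leaving out genes on the X and Y chromosomes and leaving out members of the lists of other tissues were added after the data were seen. So were 2 further gene lists, of mesenchymal matrix genes and of X-linked genes that escape inactivation, the grouping of genes by symbol stem, and the windows of genes around Sox11.

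The procedure was tested on simulated data for the comparison of the 2 arrays, drawn around the mean level of each probe set with a spread that depended on level. That spread was taken from the log2 ratios between the 2 real arrays, since there was no replicate. It is therefore not the noise between replicates, and the count of unchanged probe sets below is no error count for the real arrays. Over 45037 probe sets, 99% of 100 probe sets shifted by 2 log2 units and 97% of 100 shifted by 1.5 were counted at 2-fold, together with 115 unchanged ones. Over 11556 genes, 100% of 50 lists shifted by 0.5 were placed above the central range, and 4% of 200 unshifted lists lay outside it. These lists were random genes with independent noise, so both values hold only for genes that do not move together. List shifts smaller than 0.5 were not simulated. On the real arrays, the 18 hybridisation control probe sets had log2 ratios from -0.06 to 0.31, with a median of 0.10. The ratio of the 3' to the 5' probe set was 1.29 in the wild type and 1.21 in the knockout for Actb, and 0.818 and 0.821 for Gapdh. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and the plots matplotlib 3.10.9.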

Results

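The series compared the retina of a wild-type mouse embryo with the retina of a Sox11 knockout littermate, both on a C57BL/6 background and both at embryonic day 18. Sox11 is a transcription factor of the SoxC family, which also holds Sox4 and Sox12, and it is expressed in differentiating neurons. Total RNA of 1 retina per genotype was amplified, labelled with biotin and hybridised to 1 Affymetrix mouse array each, so 45037 probe sets, besides 64 controls, were measured on 2 arrays. There was no replicate of either genotype: no error or test can be given, and every difference below is a difference between 2 arrays. The number of arrays limits the precision. Both arrays were scaled alike, with a mean of 100 after 2% of the probe sets were left out at each end. Their median intensities were 17.6 in the wild type and 19.7 in the knockout. Across the 23581 probe sets past the low-value filter, Pearson's r between the log2 values of the arrays was 0.979; probe sets are not independent replicates.

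The question put by the design was which transcripts differ in the retina when Sox11 is missing. On the knockout array, genes of rod photoreceptors were lower, with a median log2 ratio of -0.77 over 10 genes, and smaller negative medians, also outside their random lists, were found for bipolar cell, Müller glia and DNA replication genes. Genes of retinal ganglion cells and horizontal cells were higher, with medians of 0.15 and 0.43. Higher by more were the lists of 4 cell types and tissues other than neural retina: periocular mesenchyme by 0.98, macrophages and microglia by 0.91, lens by 0.68 and pigment epithelium by 0.60. Surface ectoderm genes were lower, by a median of -0.37, and endothelial genes, at 0.20, lay inside their random lists. The arrays also differed in sex-linked transcripts, with Y-linked signal in the wild type and Xist in the knockout. All ratios are knockout minus wild type on the log2(intensity + 5) scale, which understates the change of low genes.

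Sox11 itself was measured by 6 probe sets, and they differed among themselves. The brightest, 1431225_at, read 3205.7 in the wild type and 252.4 in the knockout, a log2 ratio of -3.64. The probe set 1453002_at gave -2.43, from 1086.8 to 198.1, and 1429051_s_at and 1429372_at gave -1.21 and -1.19. The probe set 1453125_at was nearly level, at 836.9 and 740.2, with a log2 ratio of -0.18. The last, 1436790_a_at, went the other way, from 328.8 to 701.7, a log2 ratio of 1.08. The median over the 6 probe sets was -1.20. The labels do not say which part of Sox11 was deleted, so a probe set outside that part checks nothing about the genotype. All 6 passing Sox4 probe sets were positive, between 0.06 and 0.48; the brightest of them gave 0.06, and the one at 0.48 lay beyond the central 95% of log2 ratios at its level (-0.38 to 0.41). The 2 passing Sox12 probe sets gave -0.04 and 0.11.

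**Figure D1:**
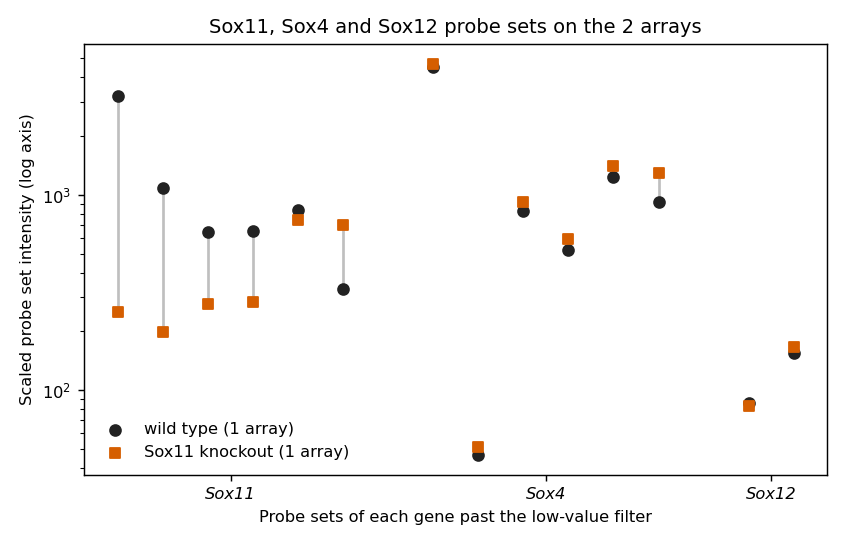
Scaled intensity (log axis) of each probe set of Sox11, Sox4 and Sox12 past the low-value filter, with the wild-type array as black circles, the knockout array as orange squares and a line joining the 2 values of a probe set. Sox11 probe sets range from a log2 ratio of -3.64 to 1.08, while those of Sox4 lie between 0.06 and 0.48.

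Past the filter, 347 probe sets were at least 2-fold higher and 94 at least 2-fold lower on the knockout array, so that 78.7% of the 2-fold differences were higher. That split depended on scaling and on the low-value filter. It was 66.6% after quantile normalization (251 higher, 126 lower) and 67.5% after loess (258 higher, 124 lower). With no low-value filter it was 59.6% (912 higher, 617 lower), and with the filter at 109.4 it was 59.3%. Most of these probe sets were dim. Of the higher ones, 275 lay in the lowest of 4 equal bands of level, and 242 had a wild-type value below the filter of 18.6; of the lower ones, 69 lay in that band and 66 had a knockout value below 18.6. The central 95% of log2 ratios ran from -0.76 to 1.18 in the lowest band and from -0.38 to 0.41 in the highest. With the filter raised to 109.4, 35 probe sets were 2-fold higher and 24 lower.

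Several of the genes furthest apart were sex-linked, matrix or lens genes, and others shared no kind. Where the dimmer array was below the filter, the ratio depends on the pseudocount, and a fold against the filter value of 18.6 is given as a lower bound. Xist, the RNA that coats the inactive X chromosome, read 12.3 in the wild type and 922.7 in the knockout, at least 49.6-fold higher. Col3a1, a fibrillar collagen, read 13.3 and 253.2, at least 13.6-fold higher, and its 2 probe sets gave log2 ratios of 1.86 and 3.82. The small proteoglycans Dcn and Lum were at least 7.17-fold and 2.87-fold higher, and Mgp, a matrix protein, at least 3.34-fold. The lens crystallin Crygd was at least 3.26-fold higher, and Crygf, measured above the filter on both arrays, went from 20.7 to 95.6, a log2 ratio of 1.97. The macrophage gene Mpeg1 and the lymphocyte kinase Zap70 were at least 2.75-fold and 2.35-fold higher. The other 3 of the 12 highest genes, Emp3, Gm9866 and Lmo7, were at least 3.09-fold, 1.88-fold and 1.23-fold higher. Probe sets of gamma crystallins can share sequence, so which family member gave the signal is uncertain.

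At the other end, the Y-linked genes Eif2s3y, Kdm5d and Uty were at least 11.5-fold, 7.01-fold and 5.64-fold lower on the knockout array. Only 2 further genes of the 12 lowest were above the filter on both arrays. Sag, the rod arrestin, went from 246.7 to 42.8, a log2 ratio of -2.40, and Tmem18, which encodes a transmembrane protein, went from 286.9 to 66.7, a log2 ratio of -2.03. Tnni1, the slow skeletal muscle troponin I, read 33.4 and 2.0, at least 1.80-fold lower. Gkn3, Etv4, Tmem151a, 2900060N12Rik, Cstdc2 and Rec8 had wild-type intensities between 19.1 for Rec8 and 29.0 for Gkn3, barely above the filter. Their bounds were 1.56-fold for Gkn3, 1.20-fold for Etv4, 1.13-fold for Tmem151a, 1.12-fold for 2900060N12Rik, 1.10-fold for Cstdc2 and 1.03-fold for Rec8. Sox11 is not among the 12 because its probe sets differ in sign.

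**Figure D2:**
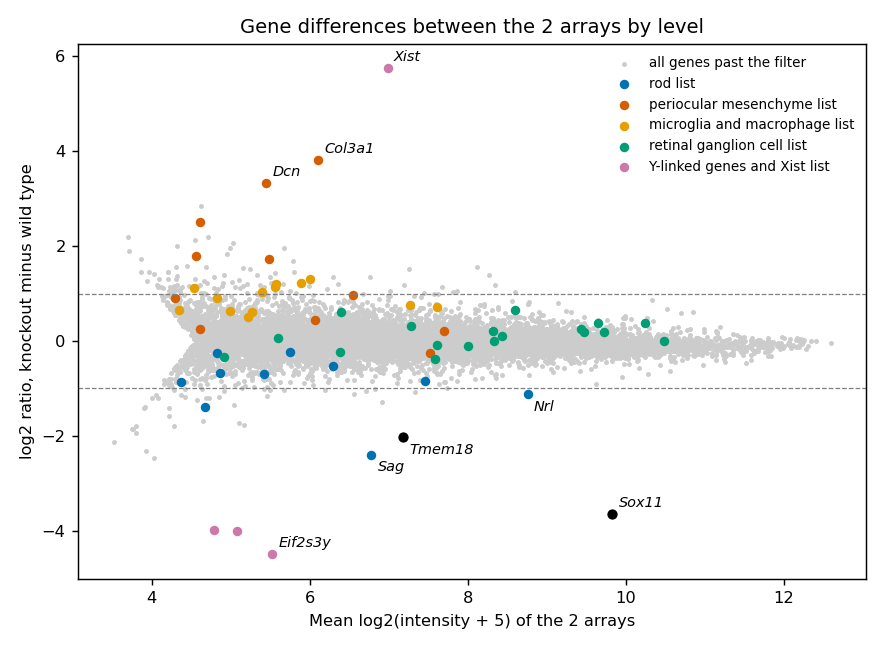
Each dot is a gene past the filter, with the mean log2(intensity + 5) of the 2 arrays on the x axis and the log2 ratio, knockout minus wild type, on the y axis; colours mark members of 5 gene lists and dashed lines mark 2-fold. The scatter widens toward low levels, rod genes such as Sag (-2.40) and Nrl (-1.12) lie below 0, and Dcn (3.33) and Col3a1 (3.82) lie far above it.

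Of 34 gene lists, 31 had at least 4 members past the filter, and 12 of them had a median outside the central 95% of 10000 random lists matched on level, 6 higher and 6 lower. If the lists, and the genes within each list, were independent, 1.55 would lie outside with no difference at all. Genes of a cell type can move together with any difference between the 2 samples, so 1.55 is not an error rate. The percentiles describe these 2 arrays only. For lists inside their random lists, the range of the median over all settings run is given. With the filter at 109.4, the lists of rods, bipolar cells, horizontal cells, pigment epithelium, macrophages and surface ectoderm had too few members for a percentile.

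Rod genes differed most among the retinal cell types. All 10 measured members were lower on the knockout array, 3 of them by 2-fold or more on the log2(intensity + 5) scale and 2 also against the filter value, and the median of -0.77 lay below all random lists (percentile 0). The 2 were Sag and Nrl, the transcription factor that sets rod fate, at 632.8 and 289.0 with a log2 ratio of -1.12. Pde6b, a subunit of the rod phosphodiesterase, read 36.5 and 10.8, with a log2 ratio of -1.39 but a bound of 1.96-fold. Cngb1, a subunit of the rod cation channel, had a log2 ratio of -0.86 (at least 1.23-fold). With intensities below the filter set to the filter value, the rod median was -0.67. Genes shared by rod and cone precursors were mixed: their median was -0.07 over 11 genes (percentile 40.9; -0.19 to 0.01 over the settings), and Rp1 and Aipl1 had log2 ratios of -0.77 and -0.72 while Mpp4 had 0.48 and Rcvrn -0.28. Without probe sets that can match several transcripts, that median was -0.19 and lay outside the random lists. Cone genes had a median of 0.16 (percentile 95.2), with Pde6c at 0.76, Thrb, the thyroid hormone receptor of cones, at 0.64 and Gngt2 at 0.35. The cone median ranged from 0.05 to 0.17 over the settings: its percentile was 98.7 after quantile normalization and 98.4 after loess, but 70.4 without probe sets that can match several transcripts and 76.0 with the filter at 109.4. The member of that list with the largest ratio, Ttr at 1.46, is transthyretin, which is made by pigment epithelium, and its wild-type intensity was only 4.4, with a bound of 1.12-fold.

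Bipolar cell and Müller glia genes were lower too, by less than rod genes. Bipolar cell genes had a median of -0.23 (percentile 0.62), with 7 of 10 lower: Car8 at -0.95 and the homeobox genes Irx5 at -0.83 and Lhx4 at -0.28, against Pcp2 at 0.86. Müller glia genes had a median of -0.19 (percentile 0.34), with 9 of 14 lower. Rlbp1, the retinaldehyde-binding protein, read 296.5 and 147.0, a log2 ratio of -0.99, the carbonic anhydrases Car14 and Car2 had -0.62 and -0.57, and Cp, ceruloplasmin, had -0.53 with its 8 probe sets between -0.53 and 0.12. Amacrine cell genes were negative in 11 of 14, but their median of -0.13 lay inside the random lists (percentile 6.44; -0.18 to -0.08 over the settings). Gad1 and Slc32a1, which make and load the transmitter GABA, had log2 ratios of -0.65 and -0.47, Tfap2a -0.44 and Tfap2c -0.28. The amacrine percentile was 1.21 after quantile normalization and 1.04 after loess, but 9.24 with the pseudocount at the pooled median and 14.4 without probe sets that can match several transcripts.

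Ganglion cell and horizontal cell genes went the other way. Retinal ganglion cell genes were higher in 13 of 18, with a median of 0.15 (percentile 99.9). The transcription factors Ebf3 and Isl2 had log2 ratios of 0.65 and 0.61 and the neurofilament gene Nefm 0.37, while Eomes, a marker of a ganglion cell subset, had -0.38. Horizontal cell genes had a median of 0.43 (percentile 99.8), with 5 of 7 higher. Onecut1, Lhx1, Onecut2 and Prox1, transcription factors of horizontal cell development, had 0.76 (at least 1.47-fold), 0.63, 0.58 and 0.43. When the median over the probe sets of a gene was taken in place of the brightest, the horizontal cell median was 0.16, inside its random lists (percentile 83.7). These lists were higher on the same array on which the mesenchyme and macrophage lists were higher by 0.98 and 0.91.

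Progenitor genes were about level, with a median of -0.05 over 17 genes (percentile 67.5; -0.08 to 0.03 over the settings). Sfrp2, a secreted Wnt antagonist, had the largest ratio at 0.78, and Id3, Fgf15 and Hes5 had -0.36, 0.25 and -0.25. Neurogenic factors and Notch ligands had a median of 0.01 over 14 genes (percentile 90.2; -0.06 to 0.03 over the settings). Atoh7, the factor required for ganglion cell formation, nevertheless read 945 and 1731, and its 2 probe sets had log2 ratios of 0.87 and 1.20. Gadd45a, a growth arrest gene, had 0.84, and Olig2 and Neurod4 had -0.29 each.

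Genes of DNA replication were slightly lower. Of the 19 measured genes of G1/S and DNA replication, 18 had a negative ratio, with a median of -0.17 (percentile 0.695) against a random median of -0.07; after quantile normalization it was -0.11, still outside. Mcm5 and Mcm7, subunits of the replicative helicase, had -0.41 and -0.31, and Rrm2, a ribonucleotide reductase subunit, had -0.63 with probe sets between -0.63 and 0.38. Gins2 was the exception at 0.38. Genes of G2/M and mitosis were also negative in 18 of 19, but their median of -0.15 lay inside the random lists (percentile 3.17; -0.18 to -0.05 over the settings), with Top2a at -0.41, Cdc20 at -0.29, Hmmr at -0.24 and Bub1b at -0.21. That list lay outside after loess (median -0.11) and against unmatched random lists, and well inside with the median over probe sets (-0.05, percentile 49.3). Targets of p53 and apoptosis genes had a median of 0.13 (percentile 93.3; 0.07 to 0.16 over the settings), led by Sesn2 at 0.53, with Mdm2 at 0.25, Ccng1 at 0.21 and Bcl2l11 at -0.28.

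Genes of the neuronal cytoskeleton and axon growth had a median of -0.12 over 20 genes (percentile 13.7). It ranged from -0.15 to -0.01 over the settings and crossed the random median: the percentile was 41.2 after loess, 63.1 without probe sets that can match several transcripts and 73.0 with the median over probe sets. Cntn2, an axonal adhesion molecule, stood apart at 1.24, from 16.1 to 44.9 (at least 2.41-fold), with both probe sets higher, while the stathmins Stmn4 and Stmn3 had -0.48 and -0.45 and Map1b 0.22. Synapse genes had a median of -0.07 over 17 genes (percentile 23.5; -0.10 to -0.03 over the settings), with Vamp2 at -0.39, Stx1a at -0.30, Sv2a at -0.23 and Cplx1 at -0.22.

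Among signalling pathways, all 7 measured Wnt feedback targets had a positive ratio, with a median of 0.24 that lay inside the random lists (percentile 91.4; 0.12 to 0.32 over the settings). The R-spondin receptor Lgr5 had the largest at 1.29, from 16.9 to 48.7 (at least 2.62-fold), followed by Wif1 at 0.73 (at least 1.47-fold), Znrf3 at 0.53 and Notum at 0.24. Without a low-value filter, or against unmatched random lists, the Wnt list lay outside. Genes of the BMP and TGF-beta pathway had a median of 0.13 (percentile 95; 0.10 to 0.27 over the settings), with the pseudoreceptor Bambi at 0.94, Bmp2 at 0.76 (at least 1.03-fold), Bmpr1b at 0.48 and Smad6 at 0.39, and this list lay outside without the low-value filter, with the filter at 109.4 and with the median over probe sets. Hedgehog pathway genes had a median of -0.02 (percentile 50.9; -0.07 to 0.08 over the settings). Gli1, a transcriptional target of the pathway, had -0.73, Shh -0.31, Ptch1 -0.25 and Boc 0.30.

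The largest positive medians were those of mesenchyme, macrophages, lens and pigment epithelium. Of 11 periocular mesenchyme genes, 10 had a positive ratio and 5 were 2-fold or more higher, also against the filter value. The median of 0.98 lay above all random lists. In the wild type, 6 members were below the filter, so they passed it only by their knockout value. With those values at the filter, the median was 0.89. Likewise, 3 macrophage and 3 pigment epithelium members, and the lens members Crygd, Cryba4 and Crygs, passed the filter only by their knockout value. Postn, periostin, had a log2 ratio of 1.79 (at least 2.09-fold) beside the collagen and proteoglycan genes Col3a1, Dcn and Lum. All 13 macrophage and microglia genes had a positive ratio, 6 by 2-fold or more and 5 of these also against the filter value, with a median of 0.91 (0.72 with values at the filter). The complement genes C1qb, C1qa and C1qc had 1.31, 1.22 and 1.20, and Laptm5, a lysosomal protein, had 1.14, although its other probe set gave -0.25. Lens genes had a median of 0.68 (0.57 with values at the filter), with 10 of 13 positive. The gamma crystallins Cryga and Crygb had 1.68 and 1.35 beside Crygd and Crygf. The 3 negative members were Cryab at -1.28, from 183.1 to 72.6, Cryaa at -0.52, and Lim2 at -0.30 (at least 1.12-fold). With the filter at 109.4, the lens median was 0.03, inside its random lists. Pigment epithelium genes had a median of 0.60 (0.37 with values at the filter, 0.40 with no low-value filter), with 8 of 9 positive, among them the pigment cell genes Mlana, Dct and Tyr at 1.15 (at least 1.12-fold), 0.91 and 0.79 (at least 1.41-fold) and Gpnmb at 0.67 (at least 1.38-fold).

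Not every surrounding tissue was higher. The surface ectoderm and cornea list had a median of -0.37 (percentile 0.565), with 5 of 7 negative: Epcam, an epithelial adhesion molecule, at -0.53, the keratins Krt15 and Krt18 at -0.49 and -0.37, and Cdh1 at -0.37. Without the low-value filter that median was -0.17, inside the random lists. Endothelium and pericyte genes had a median of 0.20 (percentile 93.6; 0.07 to 0.46 over the settings), with Esam at 1.10 (at least 1.34-fold), Rgs5 at 0.66 and Pdgfrb at 0.58 against Kdr, the vascular endothelial growth factor receptor, at -0.56. This list lay outside its random lists with the median over probe sets and without probe sets that can match several transcripts. The ciliary margin list had a median of 0.09 (percentile 86.2; 0.06 to 0.21 over the settings), led by Wfdc1 at 1.35, with Tgfb1i1 at 0.68, Gja1 at 0.54 and Otx1 at 0.37; it lay outside without those probe sets. Genes of astrocytes and oligodendrocytes had a median of -0.08 over 4 genes (percentile 27.8; -0.27 to -0.02 over the settings), and of 0.06 with values below the filter set to the filter value. Pdgfra, a receptor of their precursors, had -1.01 and, with its other probe set, -0.31, Aldh1l1 0.64 (at least 1.23-fold), Gfap -0.38 (at least 1.09-fold) and Mbp 0.21. Of the erythroid list only Hba-a2 passed the filter, at -0.21. Of the muscle list, Acta1 and Mylpf had 0.24 and 0.11; for Tnni1 only the bound above can be given.

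The list of Y-linked genes and Xist, whose members went in opposite directions, had a median of -3.98 over 4 genes (percentile 0). It was -2.37 with values below the filter set to the filter value. The genes and the genotype separated the 2 arrays in the same way, so every difference reported here is also a difference between an array with Y-linked signal and an array with Xist. Without genes on the X and Y chromosomes, 334 probe sets were 2-fold higher and 88 lower. Without the members of the lists of other tissues, 323 were higher and 91 lower. That left 23484 of 23581 probe sets, and genes outside the lists, such as Mgp and Mpeg1, stayed in. The count therefore does not measure how much other tissues contributed.

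Stress and reference lists lay inside their random lists. Immediate early genes had a median of 0.08 (percentile 71.6; -0.15 to 0.09 over the settings), with Ccn1 at 0.79 (at least 1.41-fold), Ier3 at -0.54, Klf4 at 0.46 (at least 1.20-fold) and Fos at 0.44. Hypoxia and glycolysis genes had a median of -0.08 (percentile 29.3; -0.11 to 0.05 over the settings), with P4ha2 at 0.72, Adm at -0.60 (at least 1.49-fold), Egln3 at 0.44 and Vegfa at -0.36. Genes of heat shock and the unfolded protein response had a median of -0.03 (percentile 52.7; -0.10 to 0.12 over the settings), with Chac1 at 0.51, Hspb1 at 0.46, Trib3 at 0.44 and Hsph1 at 0.42. Common reference genes had a median of -0.06 (percentile 63.9; -0.09 to 0.03 over the settings). Gusb and B2m, at 0.65 and 0.50, were the furthest from level among them, ahead of Pgk1 at -0.21 and Tbp at -0.15.

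**Figure D3:**
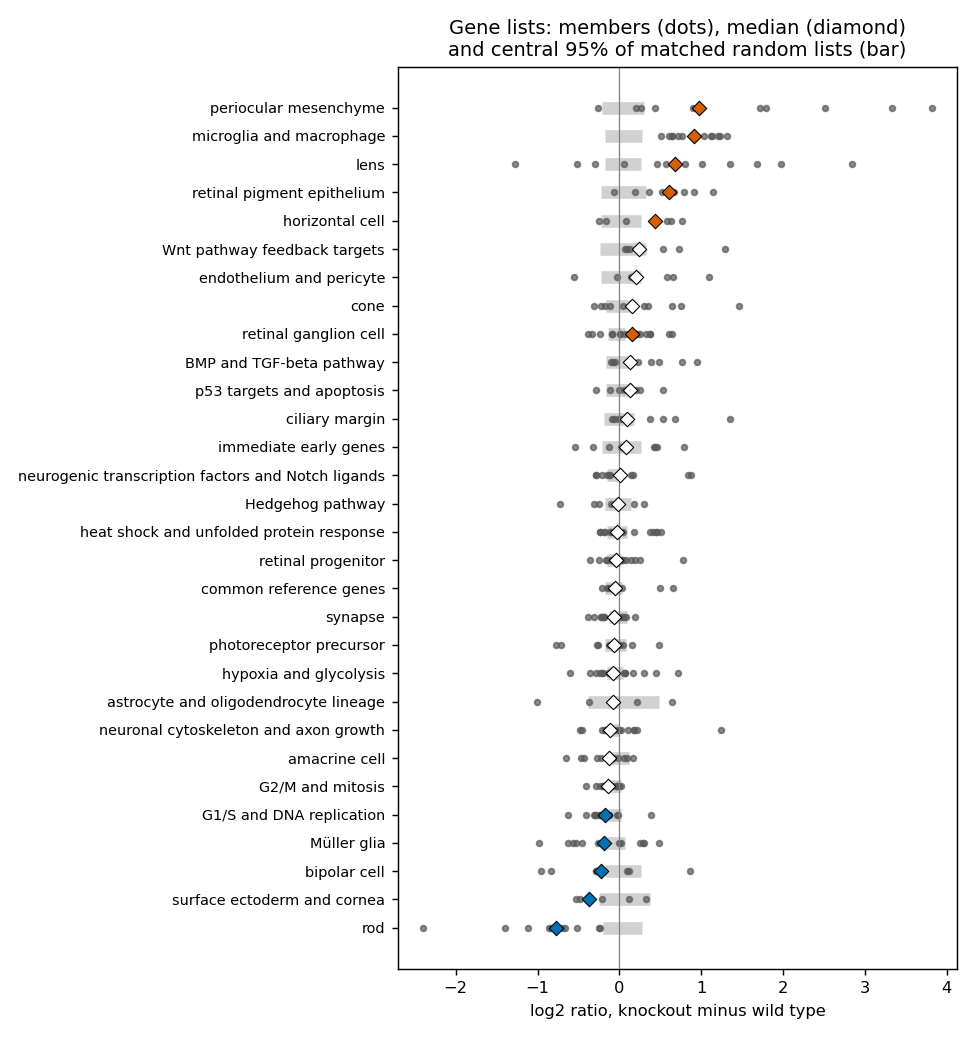
Log2 ratio, knockout minus wild type, on the x axis for 30 gene lists, with members as grey dots, the median as a diamond (orange above and blue below the central 95% of matched random lists, white inside) and that central range as a grey bar; the Y-linked and Xist list is not drawn. Medians run from -0.77 for rods to 0.98 for periocular mesenchyme.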

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

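The counts without genes on the X and Y chromosomes and without members of the lists of other tissues were chosen after the result was seen; the other settings were planned. The numbers of 2-fold probe sets depended most on how dim values were treated: 606 higher and 166 lower with no pseudocount, 84 and 37 with a pseudocount at the pooled median, 912 and 617 with no low-value filter, and 35 and 24 with the filter at 109.4, which counts fewer probe sets by construction. More were higher than lower under every setting run, and the counts were within 1.5 times the main ones under the other settings. The Sox11 log2 ratio was -1.20 with the median over its 6 probe sets, which mixes probe sets that disagree, and between -3.67 and -3.57 under the other settings. The number of lists outside their random lists was 12 to 15 under all settings but the filter at 109.4, where 5 of 21 lists with a percentile were outside, 4 of them shared with the 12 (ganglion cell, Müller glia, DNA replication and mesenchyme). Medians of the 11 lists outside other than the sex-linked one kept their sign wherever they could be computed: rods from -0.99 to -0.52, Müller glia from -0.22 to -0.17, bipolar cells from -0.32 to -0.16, DNA replication from -0.22 to -0.11, surface ectoderm from -0.49 to -0.17, ganglion cells from 0.11 to 0.19, horizontal cells from 0.16 to 0.51, mesenchyme from 0.85 to 1.46, macrophages from 0.70 to 1.11, pigment epithelium from 0.40 to 0.67 and lens from 0.03 to 0.74. Of 1388 values of 167 named genes under alternatives, 96 moved by more than the SD of 0.26 between probe sets of a gene, and none of a gene with a 2-fold difference changed sign. Where an array was near background, mainly below 18.6, ratios rest on the pseudocount. No paired analysis was possible because each genotype had 1 array.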

Other observations

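Chosen only after results were seen were the bright genes, gene families and X-linked genes described first, and the tests on progenitor and bipolar cell genes, on DNA replication genes, on Xist, on Cryaa, on surface ectoderm and on the nearest 10 genes to each side of Sox11; the tests on rods after loess, on further mesenchymal genes and on 50 genes to each side were set before their results were seen. Among genes that reached 109.4 on an array and whose probe sets shared a sign, several outside the lists were 2-fold or more higher on the knockout array. Crhbp, which binds corticotropin-releasing hormone, read 156.9 and 474.7 (log2 ratio 1.57), and Efemp1, a matrix glycoprotein, read 85.6 and 253.9 (1.51). Ednrb, the endothelin receptor B, had 1.39, with the lowest of its 3 probe sets at 1.06, Ghr, the growth hormone receptor, 1.35, with the lowest of its 3 at only 0.51, Selenop, a selenium carrier, 1.17, Fat4, an atypical cadherin, 1.13, and Igfbp5 1.05. Lower ones were Glra2, a glycine receptor subunit, at -1.11, Rgl2 at -1.07 and Inpp5j, an inositol phosphatase, at -1.06. Cnp, an enzyme of myelinating glia that read 1075.1 and 571.6, had -0.91, with its 3 probe sets between -0.91 and -0.24, and Epas1, a hypoxia-inducible factor, had -0.90 with both probe sets lower.

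When genes were grouped by the stem of their symbol, 14 of 134 families with at least 10 members lay outside the central 95% of 2000 random lists each, 8 above and 6 below. By chance, 6.7 would be outside if the families, and the genes within each, were independent. The furthest from its random lists was Pcdhb, the beta cluster of protocadherins, cell-surface adhesion molecules that neurons express in different combinations. Of its 13 measured members, 12 were lower on the knockout array, with a median of -0.61 (percentile 0), and all 13 were lower after loess, with a median of -0.70. Pcdhb19 read 40.7 and 19.0 (-0.93), Pcdhb22 read 81.5 and 44.1 (-0.82), and Pcdhb7 was level at 70.6 and 70.8. Pcdhb10, Pcdhb12 and Pcdhb5 passed the filter only by their wild-type value, with bounds of 1.61-fold, 1.30-fold and 1.03-fold. Only 2 members passed the filter of 109.4, and probe sets of such similar genes can share sequence, so single members are uncertain. The 10 protocadherins outside the clusters had a median of -0.02 (percentile 36.8). No gene of the alpha or gamma cluster had a value here, so whether the shift is particular to the beta cluster was not tested. All 4 X-linked genes that escape inactivation were higher, with Kdm6a at 0.74 and Eif2s3x at 0.49, while the 381 X-linked genes other than Xist, these 4 included, had a median of 0.00.

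Rod, bipolar cell and Müller glia lists were lower on the knockout array, while the ganglion cell list was higher. A scaling difference that depends on level is argued against for rods by their median, which was -0.83 after loess. Their percentile stayed at 0, but the random lists were already matched on level, so that percentile adds little. A smaller share of retinal RNA is argued against as the whole cause for rods, at -0.77, by the progenitor median of -0.0469. That gap was above the SD of progenitor members (0.25) in all 10 settings, though above the SD of rod members (0.63) in only 7. A smaller share alone would lower every retinal list. The ganglion and horizontal cell medians, at 0.15 and 0.43, were positive, which argues against it as the only difference, while the amacrine median was -0.13. As a contributor, a smaller share stays open for Müller glia and for bipolar cells, at -0.23. A less advanced stage of the knockout retina cannot be told apart from genotype with 1 embryo each. Atoh7 at 0.87 and the ganglion cell median of 0.15 go with it, while the DNA replication median of -0.17 goes against it. The median of G2/M and mitosis genes, at -0.15, was also negative but inside its random lists. A smaller retinal share could lower both medians, but that share was not estimated. The sex of the embryos cannot be told apart from genotype either, because Xist, with a log2 ratio of 5.74, separates the same 2 arrays. An effect of Sox11 on the genes of these lists stays open beside it. The lists measure transcripts, and whether these retinas held the cells they are named after was not examined.

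The lists of periocular mesenchyme, macrophages, lens and pigment epithelium were higher on the knockout array. Lens tissue in the knockout sample stays undecided: Cryaa, an alpha crystallin abundant in lens, was not higher, at -0.52, and lay inside the central 95% of log2 ratios at its level (-0.53 to 0.77), and Cryab, at -1.28, lay below its range, but the retina makes both, which could hide some lens RNA. Whether a smaller retinal share raised every other cell type alike stays undecided: the surface ectoderm list, at -0.37, went the other way, but its members read only 23.7 to 51.5, close to the filter, and its call is lost without the filter. Mesenchymal tissue in the knockout sample goes with 84.6% of 13 further matrix genes outside the fixed list being higher, such as Pcolce at 1.23, Bgn at 1.21 and Sparc at 0.49. That list was added after matrix genes had been seen to be higher and holds genes of the same kind, so a high share adds little. It cannot tell mesenchymal tissue from higher expression of matrix genes in other cells. Whether any such tissue was present, and if so was carried over in dissection or belongs to the mutant eye, remains open, since 1 retina per genotype was measured.

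Near Sox11 in the gene order of GRCm38.p6, Tmem18, Gm9866 and 2900060N12Rik were 2-fold apart on the log2(intensity + 5) scale, but the bounds of Gm9866 and 2900060N12Rik were only 1.88-fold and 1.12-fold, and 2900060N12Rik had -0.93 with the pseudocount at the pooled median. Alleles carried along with the mutation from another strain may alter probe binding or expression nearby, although the labels name C57BL/6 for both embryos. Among the 50 measured genes on each side, these 3 of 100 were 2-fold apart, percentile 88.5 of 9251 such windows, whose 95th percentile was 4%, so this explanation stays undecided. An effect of the edited locus on its nearest neighbours was examined with 10 measured genes on each side: the same 3 of 20 were 2-fold apart, percentile 99.6 of 10771 windows. Because these genes were noticed first, and only Tmem18 was above the filter on both arrays, that value decides nothing. Both windows took the brightest probe set of each gene. Among the nearest 10 genes on each side, Adi1, Acp1 and Id2 gave 0.72, 0.04 and -0.06 by that probe set. The lowest of their probe sets gave -2.42, -1.80 and -1.09. How often probe sets of a gene disagree in this way in other windows was not examined.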
